A study of Arabidopsis thaliana with 24 samples.

How the data were processed

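RNA sequencing had been run on roots of 5-day-old Arabidopsis thaliana seedlings from 4 F1 lines, each treated for 8 h with 1 µM abscisic acid (ABA) or with a mock solution. Every line carried a transgene in which the yeast upstream activating sequence drives abi1-1, a dominant form of the protein phosphatase ABI1 that blocks ABA signalling where it is made. The transgene line had been crossed to the accession C24, which brings no driver and served as the control, or to 1 of the enhancer trap lines J0571, J1721 and Q0990, each of which makes the activator in its own set of cells. J0571 is widely used as a driver for ground tissue and Q0990 for the stele; the labels do not name the cells for any of the lines, and no cell type was assigned to a line here. Roots of about 1 cm from 50 to 100 seedlings were pooled for each sample, under 16 h of light per day, and each of the 8 groups held 3 samples. The labels do not say whether the pools came from separate sowings, so the p-values measure the spread between these pools.

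RNA had been extracted with RNeasy columns and libraries prepared with a NEBNext Ultra kit for paired reads of 150 bases, per the labels' protocols. The authors deposited raw counts of reads per gene for all 24 libraries in one table, and the submitters' processing notes name HISAT2 and HTSeq. Their versions, the genome build, the annotation and the strand setting of the counting are not given in the sources used here, so reads from overlapping or antisense genes, and from near-identical gene copies, may not have been told apart. The table held 34218 features, of which 32548 matched a locus in the RefSeq gene table of assembly TAIR10.1 and 10804 had a gene name there. That table was used for names and for which genes neighbour each other, and no coordinates are given. Every count column belonged to 1 of the 24 libraries.

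Library totals ran from 38542817 counts in C24 mock library 1 to 61555387 in J0571 ABA library 3. The most abundant gene took between 0.97 and 1.9% of a library. Replicates of every group differed by more than counting noise: over genes with at least 20 counts in a pair, chi-square divided by its degrees of freedom was 6.79 to 34.8, so no library was counted as a copy of another. Floors and bounds from a count of 0 cover counting error only.

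Counts were normalized by trimmed mean of M values and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) in 1 quasi-likelihood fit of all 24 libraries with 8 group means, after edgeR's own filter on low counts, which left 21315 genes. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were the ABA response (ABA minus mock) in each line, their average over the 4 lines, the difference in ABA response between lines (an interaction), and the difference of each driver line from C24 in mock libraries. Levels are in CPM on normalized library sizes, given as mean and standard deviation over 3 libraries, and changes are log2 values with their standard error from the fit. Folds against groups with no counts were computed against a floor of 3 counts over the group. Genes with 1 to 3 counts in a group are given as levels.

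The following gene lists were fixed before the data were examined: PP2C phosphatases, ABA receptors, ABA transcription factors and kinases, LEA and dehydration genes, ABA metabolism and transport, VND factors and xylem regulators, secondary wall and vessel death, stele patterning, Casparian strip, suberin, root hair and epidermis, root cap, phloem, cell division and meristem, shoot and chloroplast, auxin response, cytokinin response, aquaporins, nitrate uptake and assimilation, iron deficiency response, circadian clock, and touch and wounding. The 22 lists had 288 members. Of these, 8 were dropped because the reference did not give their locus the symbol written in the list, and 261 were measured. Each list was tested with fry, which asks whether its genes move on balance in 1 direction and does not compare them with other genes, adjusted over the 22 lists within a comparison. Camera with a correlation estimated from the data was the alternative. Counts of members called are also given as adjusted over the list alone where that count differs.

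The strength of the ABA response in each driver line was compared with C24 over genes called in the average response with an absolute log2 change of at least 1, by the median interaction value and fry, adjusted over these tests. The genes named in the text were fixed by rule: the 10 largest rises and falls of the C24 response and of each difference in response from C24, the 5 of each driver line's response and the 8 of each mock difference. They were taken among genes called at a mean log2 CPM of at least 1 and, for ABA responses and mock differences, without overlap between replicates. Members of the lists could be named, ABI1 always was, and organelle genes and genes without a name could be counted without being named.

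The alternatives were relative log expression normalization, DESeq2 1.42.0, no filter on low counts, a filter at 1 CPM in 3 libraries, an absolute log2 change of at least 1, fits of only the groups compared, the replicate number as a block, other choices of genes for the strength comparison, and leaving out each library in turn. Leaving out libraries for the gene lists was added after the data were seen. Other splits of the libraries were refitted, 10 where 3 libraries stood against 3 and 30 drawn at random otherwise. The tests were checked on simulated counts drawn from the real means with 200 changed genes. For the C24 response (21094 genes), edgeR recovered 70.1, 92.5 and 100% of changes of 1.5-, 2- and 4-fold, and 11 of 186 calls were false. For a difference in response (21089 genes) it recovered 34.3, 82.1 and 98.5%, and 6 of 149 calls were false.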

Results

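Transcript levels were measured in root samples of 24 pools of seedlings. The pools formed 8 groups of 3, given by 4 F1 lines and by ABA or mock treatment. All 4 lines carried the abi1-1 transgene, which is switched on only where an enhancer trap driver supplies its activator, so that the C24 cross tests the response with the transgene silent and the J0571, J1721 and Q0990 crosses test it with ABA signalling blocked in the cells of that driver. Depth was similar across libraries, at 38542817 to 61555387 counts per library. Treatment was the main difference between libraries: the first principal component held 53.1% of the variance and parted every ABA library from every mock library, while the second held 5.6%. Mock library 1 stood apart from its replicates on the second component in each line. It lay at 40.4 against 3.31 and 7.89 in C24 and at 27.4 against 1.25 and 3.08 in Q0990. The values were -30.5 against -13.3 and -16.4 in J0571 and -15.9 against 8.66 and 2.86 in J1721. Counts without these libraries are given where they change by over 1.5 times.

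**Figure D1:**
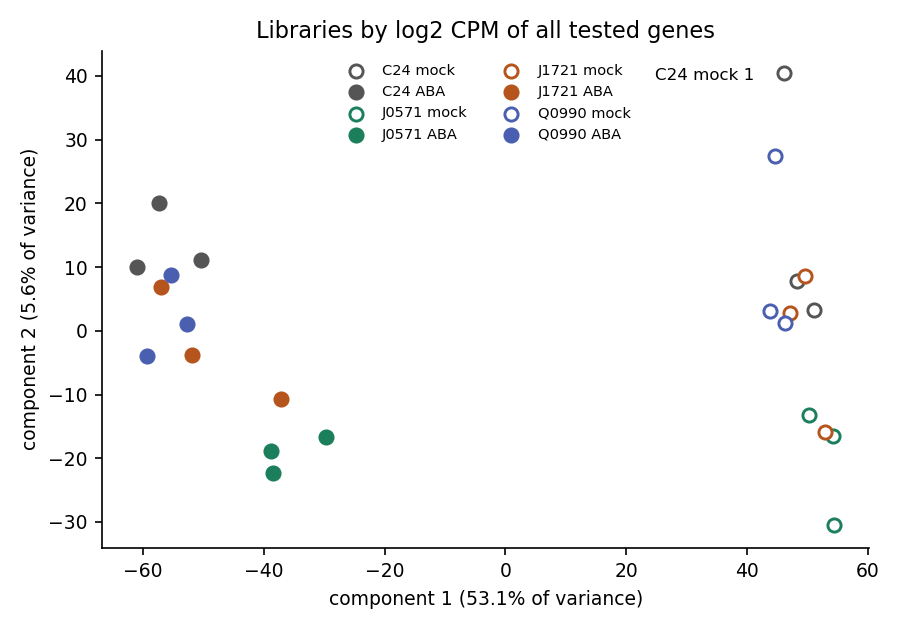
Principal components of log2 CPM for the 24 libraries, with mock libraries as open and ABA libraries as filled symbols and 1 colour per line. The first component (horizontal axis, 53.1% of the variance) separates ABA from mock in all 4 lines.

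ABI1, the gene from which the transgene derives, was itself raised by ABA in every line. In C24 it went from 97.7 ± 6.45 CPM in mock to 325 ± 50.1 CPM with ABA (SD, n = 3 libraries per group here and throughout), a log2 change of 1.73 ± 0.12 (SE) with an adjusted p of 6.94e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That test is behind every adjusted p of a gene in this text unless DESeq2 is named with it. The log2 change was 1.41 in J0571, 1.79 in J1721 and 1.83 in Q0990. In mock libraries ABI1 lay at 115 ± 2.2 CPM in J0571, 103 ± 1.4 CPM in J1721 and 111 ± 6.35 CPM in Q0990, and none of these differed from C24 (adjusted p = 0.478, 0.991 and 0.91). The counts do not separate transcripts of the transgene from those of the native gene, so they give no measure of how strongly each driver worked.

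**Figure D2:**
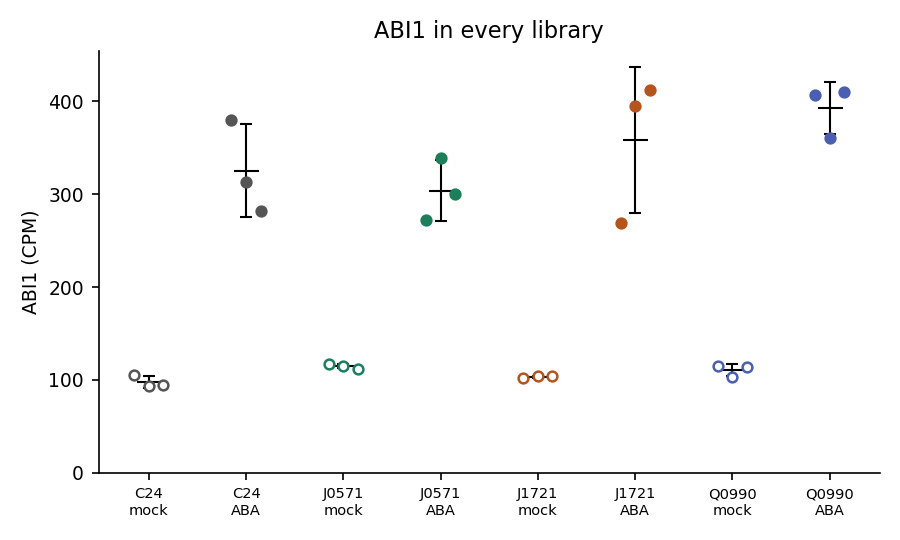
ABI1 level in CPM for each library (points) with the mean and SD of each group of 3. The ABA groups, at means of 304 to 393 CPM, all lie above the mock groups, at 97.7 to 115 CPM.

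The response of the C24 cross to ABA was broad, and LEA and dehydration genes were among the largest rises. RD20, a lipid droplet protein gene induced by drought, had no counts in the C24 mock libraries and 13.4 ± 4.16 CPM with ABA, at least 589-fold higher. LEA7, which encodes a late embryogenesis abundant (LEA) protein, went from 0.218 CPM to 878 ± 55.6 CPM, and RD29B (LTI65 in the reference), a classic ABA marker, from 0.669 CPM to 396 ± 26.9 CPM. BGLU24, a beta-glucosidase gene, rose by 7.97 ± 0.20 on the log2 scale to 93.8 ± 10.8 CPM, and the unnamed locus AT3G02480 rose by 7.71 ± 0.28. Among the largest falls were AT3G27950 at -5.75 ± 0.30, the aliphatic glucosinolate gene CYP83A1 at -4.98 ± 0.66, the GDSL lipase gene GLIP2 at -4.66 ± 0.25, EARLI1 at -4.14 ± 0.56 and the peptide transporter gene PTR3 at -3.94 ± 0.28. In all, 7252 of the 21315 genes tested were called, 3969 higher and 3283 lower. Replicates did not overlap for 43.1% of all genes, where chance gives 10%.

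In C24 the repressors of the ABA pathway rose and several of its receptor genes fell. All 9 measured PP2C phosphatase genes, which encode repressors of the pathway, rose (fry adjusted p = 1.03e-07; adjusted p = 0.0322 with an estimated correlation), led by HAI2 at 7.20 ± 0.79, HAI1 at 4.85 ± 0.42, ABI2 at 2.52 ± 0.23 and HAB1 at 1.81 ± 0.14. Of 11 receptor genes, 5 fell and 2 rose (6 and 2 adjusted over the list alone; fry adjusted p = 6.7e-08; adjusted p = 0.0322 with an estimated correlation). PYL6 fell by 3.47 ± 0.14, PYL4 by 2.05 ± 0.13 and PYL5 by 1.73 ± 0.17, whereas PYL2 and PYL3 rose by 0.71 ± 0.15 and 2.57 ± 0.38. Of 15 transcription factor and kinase genes, 10 rose, among them HB7 (2.96 ± 0.20), AFP1 (2.88 ± 0.23), RD26 (2.37 ± 0.24) and ABF2 (1.22 ± 0.13); the list was called at a fry adjusted p of 1.63e-06, with adjusted p = 0.082 with an estimated correlation. Of 13 genes of ABA metabolism and transport, 6 rose, among them the biosynthesis gene NCED3 (2.07 ± 0.16), the catabolism gene CYP707A1 (2.91 ± 0.19) and the exporter gene ABCG25 (0.60 ± 0.12); fry gave an adjusted p of 2.52e-07, and adjusted p = 0.0671 with an estimated correlation. All 26 LEA and dehydration genes rose (fry adjusted p = 3.34e-13; adjusted p = 1.22e-05 with an estimated correlation), with a median log2 change of 3.03 (the same with genes absent from mock libraries at their lower bounds). RAB18 rose by 6.67 ± 0.35, KIN1 by 5.24 ± 0.19, RD29A (LTI78) by 2.86 ± 0.13 and the proline synthesis gene P5CS1 by 1.73 ± 0.08.

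Genes of water-conducting and barrier tissues rose as well. Of 18 genes of secondary wall formation and vessel death, 14 rose (16 adjusted over the list alone), including the cellulose synthase genes CESA4 (0.89 ± 0.10), CESA7 (1.14 ± 0.12) and CESA8 (1.17 ± 0.12) and the nuclease gene BFN1 (2.92 ± 0.20); fry gave an adjusted p of 6.28e-08, and adjusted p = 0.0375 with an estimated correlation. Of 13 VND factors and other xylem regulators, 9 rose, among them MYB46 (1.2 ± 0.14), VNI2 (1.05 ± 0.13) and VND7 (0.83 ± 0.19), at a fry adjusted p of 4.78e-07 and adjusted p = 0.082 with an estimated correlation. Suberin genes rose in 15 of 17 cases, with the acyltransferase genes GPAT5 (1.76 ± 0.11) and ASFT (1.77 ± 0.09), the transporter gene ABCG6 (2.05 ± 0.12) and the regulator MYB41 (2.57 ± 0.31), while MYB39 fell by 0.41 ± 0.14 (fry adjusted p = 4.85e-10; adjusted p = 0.00386 with an estimated correlation). Of 18 aquaporin genes, 15 rose, led by TIP2;3 (1.98 ± 0.13) and PIP2;3 (1.22 ± 0.11), and PIP1;5 fell by 0.42 ± 0.13 (fry adjusted p = 5.31e-08; adjusted p = 0.0401 with an estimated correlation). Of 8 Casparian strip genes, 4 rose, CASP5 by 1.60 ± 0.20 and CASP1, MYB36 and PER64 by 0.24 to 0.30. The list was called at a fry adjusted p of 0.0402, with adjusted p = 0.802 with an estimated correlation, and lost the call without ABA library 1 (0.113), ABA library 2 (0.101), mock library 2 (0.0573) or mock library 3 (0.228) of C24; over all alternatives the adjusted p ran from 0.0118 to 0.802.

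The root hair, touch, clock and iron deficiency lists were also called in C24. Of 11 root hair and epidermis genes, 7 rose and 1 fell, with the proline-rich wall protein gene PRP1 at 2.66 ± 0.20, the regulator RSL4 at 0.80 ± 0.12 and its relative RSL2 at -0.79 ± 0.22 (fry adjusted p = 0.000138; adjusted p = 0.356 with an estimated correlation). Of 9 touch and wounding genes, 5 rose (6 adjusted over the list alone), led by the storage protein gene VSP2 at 4.65 ± 0.42 (fry adjusted p = 1.34e-05; adjusted p = 0.236 with an estimated correlation). Of 10 clock genes, the morning genes CCA1 (2.45 ± 0.29) and LHY (1.25 ± 0.39) and the evening gene LUX (0.26 ± 0.06) rose (fry adjusted p = 0.00223; adjusted p = 0.613 with an estimated correlation). Of 9 iron deficiency genes, 4 fell, including the iron transporter gene IRT1 at -1.83 ± 0.27 and the ferric reductase gene FRO2 at -1.03 ± 0.25, and BHLH38 rose by 0.62 ± 0.18. That list had a fry adjusted p of 0.0402, with adjusted p = 0.636 with an estimated correlation, and lost the call without ABA library 1 (0.119), ABA library 2 (0.148), mock library 2 (0.0671) or mock library 3 (0.11) of C24; over all alternatives the adjusted p ran from 0.00716 to 0.636.

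The other 8 lists were not called in C24. Stele patterning genes split, with 2 of 16 raised (MP by 0.67 ± 0.12 and TMO5 by 0.44 ± 0.08) and 4 lowered (6 adjusted over the list alone), SHR, LHW, T5L1 and ACL5, by 0.19 to 0.48; fry gave an adjusted p of 0.341 for 1 direction and 2.54e-12 for change in either direction. Of 10 cytokinin response genes 2 rose and 1 fell (2 and 3 adjusted over the list alone), with ARR16 up by 2.2 ± 0.26 and ARR15 down by 1.23 ± 0.45 (adjusted p = 0.869 for 1 direction and 7.4e-05 for either). Of 15 cell division genes, 4 rose (3 adjusted over the list alone), by 0.25 to 0.29 for CYCB1;4, CDKB2;1 and KNOLLE (adjusted p = 0.164). Nitrate genes had 2 raised and 1 lowered of 7 (3 and 1 adjusted over the list alone), with the reductase gene NIA2 up by 1.28 ± 0.24 and the xylem-loading transporter gene NRT1.5 down by 1.27 ± 0.22 (adjusted p = 0.24). Of 11 auxin response genes, GH3.3 and GH3.5 fell, by 1.53 ± 0.30 and 0.61 ± 0.09, and IAA2 rose by 0.21 ± 0.08, a call lost when adjusted over the list alone, which left 0 raised and 2 lowered (list adjusted p = 0.118). RBCS1A and LHCA1 fell, by 1.14 ± 0.39 and 0.74 ± 0.21, among 4 shoot and chloroplast genes (adjusted p = 0.0846). Of 7 phloem genes, the sucrose transporter gene SUC2 rose by 1.15 ± 0.18 (adjusted p = 0.341), and none of 4 root cap genes was called (adjusted p = 0.311). For the phloem and cytokinin lists the median was negative and the mean and the test were positive, and for stele patterning the median and the test were negative and the mean was 0.004.

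In J0571, 5169 genes responded to ABA, 3065 higher and 2104 lower. RD29B went from 0.281 CPM to 174 ± 32.5 CPM and LEA7 from 0.347 CPM to 388 ± 54.7 CPM. RD20 was at least 634-fold higher. Among the largest falls were CYP83A1 at -5.78 ± 0.65, MAM1 at -4.45 ± 0.60 and BCAT4 at -3.97 ± 0.64, which all encode enzymes of aliphatic glucosinolate synthesis. All 9 PP2C genes and 23 of 26 LEA and dehydration genes (24 adjusted over the list alone) rose, the latter with a median log2 change of 2.27 (2.12 with genes absent from mock libraries set at their lower bounds) and a fry adjusted p of 3.73e-12. Suberin genes rose in 13 of 17 cases (15 adjusted over the list alone; fry adjusted p = 7.3e-09; adjusted p = 0.00517 with an estimated correlation) and secondary wall genes in 16 of 18 (17 adjusted over the list alone; fry adjusted p = 4.41e-07; adjusted p = 0.0429 with an estimated correlation). Aquaporin genes rose in 15 of 18 cases (fry adjusted p = 1.27e-06; adjusted p = 0.0662 with an estimated correlation). Of the root hair list, 1 gene rose and 1 fell, and the list was not called (adjusted p = 0.542).

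In J1721, 6089 genes responded, 3377 higher and 2712 lower. RD20 was at least 655-fold higher, GLIP2 fell by 5.14 ± 0.27 and PTR3 by 3.83 ± 0.27. All 9 PP2C genes, 25 of 26 LEA and dehydration genes (fry adjusted p = 4.87e-13) and 15 of 17 suberin genes (fry adjusted p = 1.27e-10; adjusted p = 0.00089 with an estimated correlation) rose, and 7 of 11 receptor genes fell while 2 rose (fry adjusted p = 1.49e-07; adjusted p = 0.0378 with an estimated correlation). Of the 13 VND factors and regulators, VNI2 rose and VND6 fell, by 1.33 ± 0.32, and the list was not called (adjusted p = 0.474, median 0.13). Of 18 secondary wall genes, 6 rose, with a median of 0.22 (fry adjusted p = 0.00134; adjusted p = 0.503 with an estimated correlation).

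In Q0990, 6651 genes responded, 3631 higher and 3020 lower. RD20 was at least 698-fold higher, and GLIP2 and AT3G27950 fell by 5.03 ± 0.26 and 6.07 on the log2 scale. All 9 PP2C genes and all 26 LEA and dehydration genes rose (fry adjusted p = 5.62e-13 for the latter), as did 15 of 17 suberin genes (fry adjusted p = 1.12e-09; adjusted p = 0.00452 with an estimated correlation). Of 11 receptor genes, 7 fell and 2 rose (fry adjusted p = 8.76e-09; adjusted p = 0.00947 with an estimated correlation). Secondary wall genes rose in 13 of 18 cases with a median of 0.58 (fry adjusted p = 1.55e-06; adjusted p = 0.0933 with an estimated correlation) and 4 of 13 xylem regulators rose (5 adjusted over the list alone; fry adjusted p = 0.00023; adjusted p = 0.405 with an estimated correlation).

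The 4 lines shared much of this response. ABA raised 2161 genes in all 4 lines and lowered 1205, where independent lists of these sizes would share 15 and 6. These lists come from separate libraries. Between any pair of lines, 78.2 to 87.4% of the shorter list of raised genes and 69.9 to 77.3% of the shorter list of lowered genes were shared, and calls of opposite sign numbered 20 when summed over all pairs. Averaged over the lines, 11772 genes were called, 5879 higher and 5893 lower.

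The question of where ABA signalling is needed was addressed by comparing the response of each driver line with that of C24. In J0571 several genes that ABA lowered in C24 fell less or not at all. XTH16, which encodes a wall-loosening xyloglucan endotransglucosylase, went from 48.6 ± 1.33 to 12.6 ± 1.26 CPM in C24 and from 49.4 ± 4.5 to 58.1 ± 5.92 CPM in J0571, a difference in response of 2.18 ± 0.15 (adjusted p = 4.8e-09). GLIP2 fell to 1.01 ± 0.302 CPM in C24 and stood at 8.03 ± 1.16 CPM in J0571 (difference 2.76 ± 0.31, adjusted p = 1.7e-05), and PTR3 fell from 4.86 ± 1.07 to 0.31 CPM in C24 against 7.11 to 4.35 ± 0.585 CPM in J0571 (3.23 ± 0.35, adjusted p = 1.1e-05). The glutathione transferase gene GSTU11 (2.70 ± 0.43) and the loci AT2G43140 (3.86 ± 0.35), AT1G64910 (3.02 ± 0.27) and AT1G10400 (2.31 ± 0.26) differed in the same direction. AT2G43140 also differed this way from C24 in J1721 and, by DESeq2, in Q0990, as did AT1G64910 in Q0990 by DESeq2. Genes with a weaker rise in J0571 included DAA1, an ATPase gene that reached 39.1 ± 2.59 CPM in C24 and 10.8 CPM in J0571 (-1.08 ± 0.18, adjusted p = 0.0021), the anion channel gene ALMT12 (18.9 ± 1.21 against 7.59 ± 0.369 CPM; -1.25 ± 0.22, adjusted p = 0.0042) and the arabinogalactan protein gene FLA6 (14.7 against 9.36 CPM; -1.72 ± 0.32, adjusted p = 0.0087). The levels of DAA1, ALMT12 and FLA6 are those with ABA. For DAA1 and FLA6 they do not match the size of the difference in response, which also rests on mock levels. In total 86 genes responded differently, 59 with a higher and 27 with a lower value in J0571. Against the mean response of the 2 other driver lines, whose libraries do not enter this difference, 58 of the 59 higher genes were ones that fell and 26 of the 27 lower genes were ones that rose. The count was 57 without C24 ABA library 3 or without J0571 mock library 1. DESeq2 called 197 genes, 91 higher and 106 lower.

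**Figure D3:**
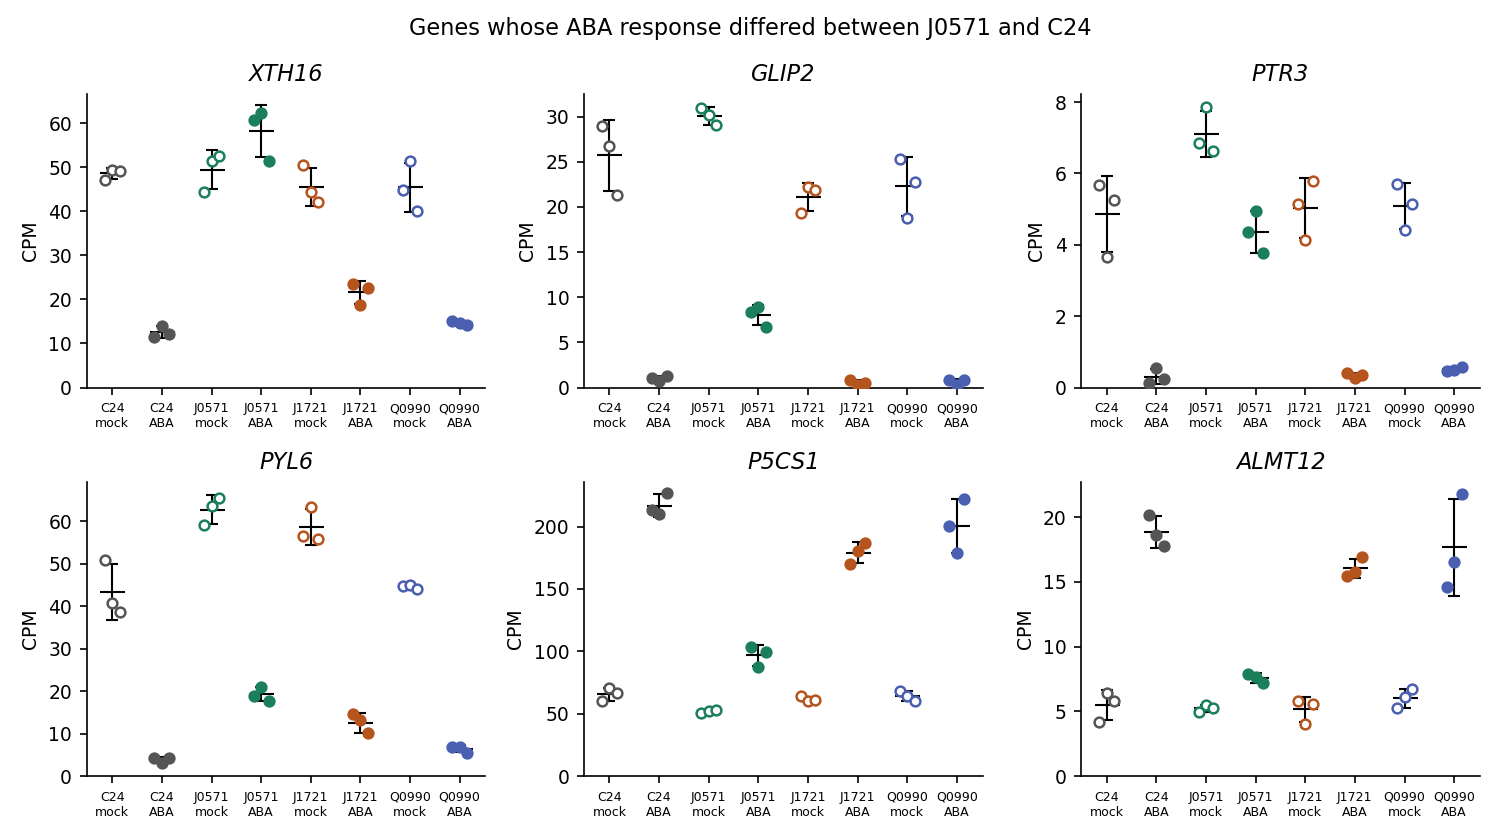
Level in CPM per library, with mean and SD of each group of 3, for XTH16, GLIP2, PTR3, PYL6, P5CS1 and ALMT12 in mock and ABA libraries of the 4 lines. With ABA, XTH16 stands at 58.1 CPM in J0571 against 12.6 CPM in C24, and ALMT12 at 7.59 against 18.9 CPM.

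The receptor genes PYL6 and PYL4 fell less in J0571 than in C24. PYL6 fell by 1.71 ± 0.12 in J0571 against 3.47 ± 0.14 in C24 (difference 1.76 ± 0.18, adjusted p = 4.27e-06) and PYL4 by 1.16 against 2.05 (0.90 ± 0.18, adjusted p = 0.0175). These were the 2 of 11 members called (4 adjusted over the list alone), and the median of the differences over the list was 0.29 (fry adjusted p = 0.0302; adjusted p = 0.0753 with an estimated correlation). As a list the receptors had 5 genes lowered and 2 raised in both lines, and the median response was -0.32 in J0571 and -0.23 in C24, opposite in order to the means of -0.26 and -0.56. LEA and dehydration genes rose less, with a median difference of -0.44 (fry adjusted p = 0.0302; adjusted p = 0.051 with an estimated correlation). P5CS1 was the member called (8 adjusted over the list alone), with a rise of 0.91 ± 0.08 against 1.73 ± 0.08 (difference -0.82 ± 0.11, adjusted p = 1.9e-04). The differences were -1.76 ± 0.54 for LEA7 and -0.63 ± 0.17 for RD29A, which did not pass the test. Root hair genes differed by a median of -0.43 (fry adjusted p = 0.0325; adjusted p = 0.0753 with an estimated correlation) with none of 11 members called (7 adjusted over the list alone); PRP1 rose by 1.57 against 2.66. All of these list calls were lost without C24 ABA library 1 (0.066), J0571 mock library 1 (0.0904) or J0571 mock library 2 (0.0523 for receptors and LEA genes, 0.0617 for root hair genes). Without J0571 ABA library 2 the receptor and root hair calls were lost (0.0625 for both), and the root hair call also without C24 ABA library 3 (0.0633), C24 mock library 1 (0.0856), C24 mock library 3 (0.0674) or J0571 ABA library 3 (0.0831). C24 ABA library 1 also held 96 counts of AT4G16215, 48 of AT2G15555 and 18 of AT2G05695, which had none in C24 ABA libraries 2 and 3. Over all alternatives the adjusted p of the 3 lists lay between 0.0184 and 0.0904.

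The response as a whole was also weaker in J0571 for the genes that ABA lowers. Over 665 genes lowered by at least 1 on the log2 scale in the average response, the median change was -1.34 in J0571 and -1.58 in C24, the median difference was 0.30 (fry adjusted p = 0.0235), and 68.7% of the genes fell less. Over 1151 raised genes the median difference was -0.20 and 68.2% rose less, which did not pass the test (adjusted p = 0.113). The call on lowered genes was lost without C24 mock library 1 (0.28, adjusted p = 0.0503), J0571 ABA library 1 (0.25, 0.0607), J0571 ABA library 2 (0.19, 0.0809), J0571 mock library 1 (0.26, 0.0545) or J0571 mock library 3 (0.25, 0.0745). Over all its alternatives the adjusted p ran from 0.00111 to 0.0809. In J1721 the median differences were -0.04 for raised and 0.20 for lowered genes (adjusted p = 0.669 and 0.101), and in Q0990 they were -0.10 and 0.05 (adjusted p = 0.628 and 0.669).

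In J1721 the response differed from C24 in the genes of xylem formation. All 18 secondary wall and vessel death genes had a lower ABA response in J1721, with a median difference of -0.46 (fry adjusted p = 0.0025; adjusted p = 0.00186 with an estimated correlation), and the VND factors and xylem regulators differed by a median of -0.47 (fry adjusted p = 0.0011; adjusted p = 0.000908 with an estimated correlation). CESA7 went from 45.9 ± 6.93 to 101 ± 14.5 CPM in C24 and from 36.0 to 42.5 ± 3.06 CPM in J1721 (difference -0.90 ± 0.17, adjusted p = 0.0227). MYB46, a master switch of secondary wall formation, went from 6.56 to 15.1 ± 1.19 CPM in C24 and from 5.17 to 5.63 ± 0.852 CPM in J1721 (-1.08 ± 0.21, adjusted p = 0.0271). CESA4 (-0.69 ± 0.14), CESA8 (-0.83 ± 0.16), IRX6 (-0.90 ± 0.17) and IRX9 (-0.76 ± 0.14) were the other members called, 5 in the wall list (11 adjusted over the list alone) and 1 among the regulators (5 adjusted over the list alone). Both list calls held without any 1 of the 12 libraries, at adjusted p values up to 0.0101 for the wall list and 0.00526 for the regulators. Calls of single members did not: that of CESA7 was lost without C24 ABA library 2 (0.114), C24 mock library 1 (0.0857) or J1721 ABA library 1 (0.0688) or 3 (0.079) or J1721 mock library 2 (0.0821) or 3 (0.0787). That of MYB46 was lost without C24 ABA library 1 (0.061) or 2 (0.115), C24 mock library 1 (0.102) or 2 (0.073), J1721 ABA library 2 (0.086) or 3 (0.0868) or J1721 mock library 1 (0.0516) or 3 (0.124). Over all alternatives the adjusted p of CESA7 ran from 0.00047 to 0.114 and that of MYB46 from 0.000946 to 0.125.

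**Figure D4:**
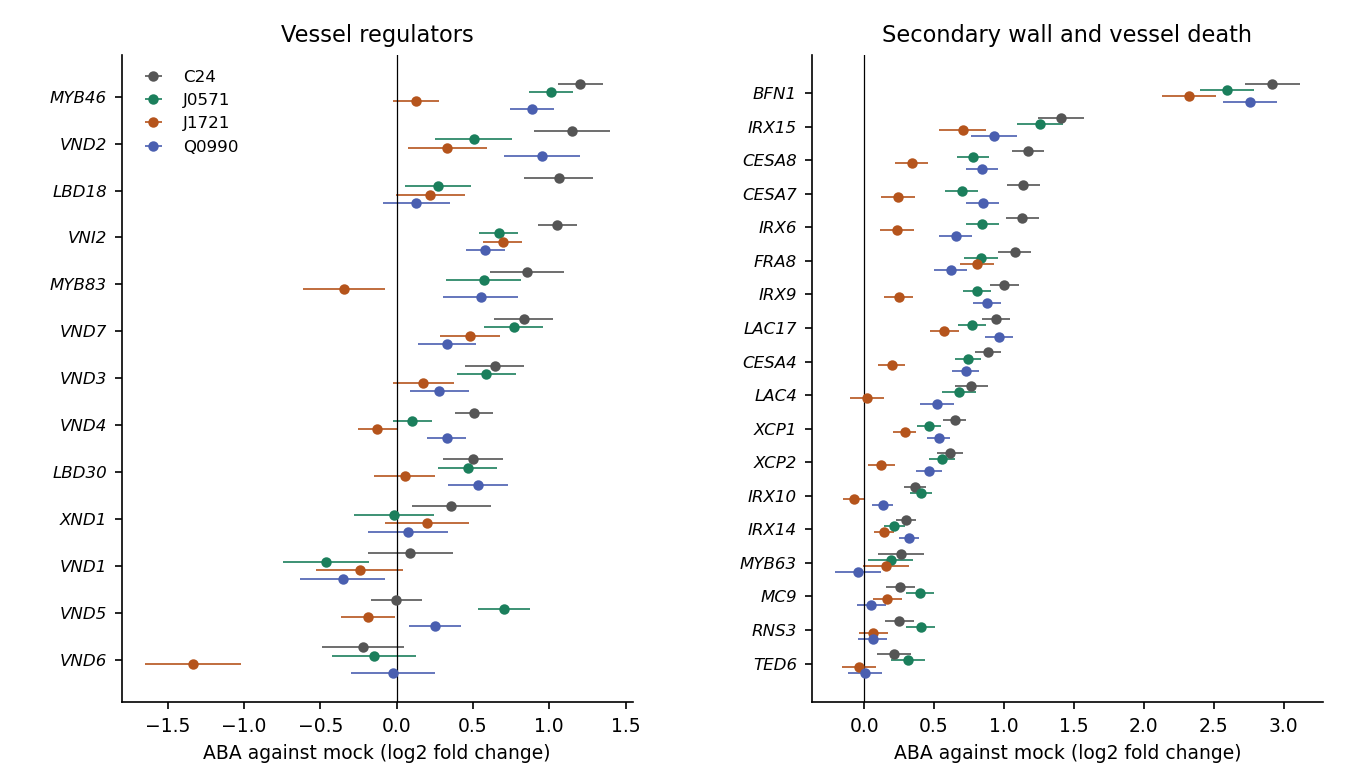
Log2 change with ABA (horizontal axis, with SE) in each of the 4 lines for the 13 VND factors and xylem regulators and the 18 secondary wall and vessel death genes. Medians in J1721 are 0.13 and 0.22, against 0.64 and 0.83 in C24.

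Outside the lists, the largest differences in J1721 were genes that fell less than in C24. AT1G05700 fell from 39.1 ± 10.3 to 1.54 CPM in C24 and from 47.2 to 17.2 ± 6.56 CPM in J1721 (3.22 ± 0.36, adjusted p = 1.4e-04), and AT2G43140 (2.56 ± 0.36), AT5G59680 (1.78) and AT5G40590 (1.63 ± 0.24) differed in the same direction. PYL6 fell by 2.21 ± 0.13 against 3.47 ± 0.14 (difference 1.26 ± 0.18, adjusted p = 0.00366). In total 36 genes responded differently, 16 with a higher and 20 with a lower value in J1721, of which 16 and 17 went against the mean response of the 2 other driver lines. DESeq2 called 62 genes, and edgeR called 15 with only the groups compared in the fit. The count fell to 8 without C24 ABA library 2, 13 without C24 mock library 1, 19 without C24 mock library 3, 17 and 22 without J1721 ABA libraries 1 and 2, and 22, 12 and 11 without J1721 mock libraries 1, 2 and 3.

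In Q0990 no gene passed the test for a difference from C24 in ABA response: edgeR called 0, with 954 genes at an unadjusted p under 0.05, and DESeq2 called 3. Those 3 genes, chosen after their values were seen, were AT2G43140 (2.22, DESeq2 adjusted p = 3.05e-06), AT1G64910 (1.62, DESeq2 adjusted p = 0.00688) and CYP82C2, which had 233 counts over all libraries. AT2G43140 was also the 1 gene called by edgeR with no filter on low counts (2.23, adjusted p = 0.0232). No list was called, the lowest adjusted p being 0.372. PYL6 fell by 2.79 ± 0.13 in Q0990 against 3.47 ± 0.14 in C24, and P5CS1 rose by 1.65 against 1.73 ± 0.08. In the simulated counts, differences in response of 1.5-fold were recovered in 34.3% of cases and those of 4-fold in 98.5%. Those changes were placed in genes at a mean of at least 1 CPM, without the structure seen among the real mock libraries. The rates therefore do not exclude differences of 4-fold in Q0990, and AT2G43140, at 2.23 with no filter, was missed by the main edgeR fit.

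Compared with each other, the driver lines differed most where J0571 was involved. The rise of P5CS1 was weaker in J0571 than in J1721 (-0.63 ± 0.11, adjusted p = 0.00712) and than in Q0990 (-0.74, adjusted p = 8.45e-04), and that of RD29A was weaker than in J1721 (-0.80 ± 0.17, adjusted p = 0.0333). The falls of PYL6 and PYL4 were smaller in J0571 than in Q0990, by 1.09 ± 0.18 (adjusted p = 0.00226) and 1.15 ± 0.18 (adjusted p = 0.00174). GLIP2 and PTR3, picked here after their values were seen, fell less in J0571 than in J1721 (3.23 and 3.12) and than in Q0990 (3.12 and 2.6). J0571 and J1721 differed in 65 genes, 42 with a higher value in J0571; without J0571 ABA library 3 the count was 43 and without J0571 mock library 1 it was 41. DESeq2 called 135, 73 of them higher. J0571 and Q0990 differed in 83 genes, 60 with a higher value in J0571, and in 55, 45, 49 and 50 without J0571 ABA library 3, J0571 mock library 1, Q0990 ABA library 1 and Q0990 mock library 1. DESeq2 called 187, 99 of them higher. Between J1721 and Q0990, 5 genes differed, all chosen after their values were seen: AT5G64120 (a peroxidase gene, 2.32 ± 0.37), AT1G05700 (2.09 ± 0.35), AT5G40590 (1.43) and AT5G23840 (1.07) were higher in J1721 and AT4G04460 lower (-0.79). That last count was 12 by DESeq2 and 0 with only the groups compared in the fit. It was 0 without J1721 ABA library 1, J1721 mock library 1 or 2, Q0990 ABA library 1 or 3 or Q0990 mock library 3, 1 without Q0990 mock library 1 or 2, and 3 without J1721 mock library 3 or Q0990 ABA library 2.

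Without ABA, J0571 differed from C24 in single genes of the endodermal barrier, sulfate transport and the glyoxylate cycle and in aquaporin genes. CASP5, which encodes a membrane scaffold protein of the Casparian strip, stood at 27.3 ± 8.42 CPM in C24 and 4.67 ± 1.29 CPM in J0571 (-2.54 ± 0.23), and the gap remained with ABA, at 82.7 ± 6.91 against 17.2 ± 2.87 CPM. The sulfate transporter gene SULTR2;1 was higher in J0571, at 67.8 ± 8.87 against 22.6 ± 7.03 CPM (1.59 ± 0.22, adjusted p = 4.5e-04), as was ICL, the isocitrate lyase gene of the glyoxylate cycle, at 51.4 ± 2.11 against 17.4 ± 1.68 CPM (1.56 ± 0.17, adjusted p = 1.4e-05). AGP30, an arabinogalactan protein gene of roots, was lower (24.7 against 51.9 CPM; -1.07 ± 0.14, adjusted p = 2.6e-04). Of 18 aquaporin genes, TIP2;3 (-0.85 ± 0.13), TIP1;1 (-0.54 ± 0.10), PIP2;1 (-0.42 ± 0.09) and TIP2;2 (-0.42 ± 0.08) were lower (11 members adjusted over the list alone); the list had a median of -0.25 and a fry adjusted p of 0.0327, with adjusted p = 0.15 with an estimated correlation, and lost the call without C24 mock library 1 (0.09) or 2 (0.0617) or J0571 mock library 1 (0.184), the highest of its alternatives, the lowest being 0.00514. The Casparian strip and iron deficiency lists did not pass (adjusted p = 0.0518 for both). In total 101 genes differed, 69 higher and 32 lower, with 30 without C24 mock library 1, 61 without C24 mock library 3, 26 without J0571 mock library 1 and 41 without J0571 mock library 2. With only the groups compared in the fit 39 genes were called, and DESeq2 called 282. Replicates did not overlap for 15.9% of all genes, where chance gives 10%.

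J1721 and Q0990 were close to C24 in mock libraries. In J1721, 9 genes differed, 6 higher and 3 lower, among them the glutathione transferase gene GSTF14 (19.6 against 4.89 CPM; 1.99 ± 0.25, adjusted p = 3.9e-04) and the germin-like gene GLP9 (12.8 against 3.65 CPM; 1.81 ± 0.22, adjusted p = 1.8e-04). The count was 5 without C24 mock library 3 or J1721 mock library 1, and 39 by DESeq2. The VND factors and xylem regulators were lower in J1721 by a median of 0.34 on the log2 scale (fry adjusted p = 0.0133; adjusted p = 0.0155 with an estimated correlation), with none of 13 called (2 adjusted over the list alone), and lost the call without C24 mock library 2 (0.0778) or J1721 mock library 1 (0.0706), with a lowest value of 0.00246 among its alternatives. In Q0990, 10 genes differed, all higher, with 6 without C24 mock library 2 17 without Q0990 mock library 1 and 16 by DESeq2, and no list was called. Several of these 10 were present or absent by line in both treatments. AT2G15555 had 2772 to 3935 counts per ABA library in J0571 and 2358 to 3306 in Q0990, against 0 to 48 in C24 and 16 to 43 in J1721. AT4G16215 had 2413 to 3094 counts in Q0990 ABA libraries against 96 in C24 ABA library 1 and 0 in C24 ABA libraries 2 and 3.

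A run of neighbouring genes on chromosome 2, found after the data were seen, was higher in J0571 than in C24 in both treatments. It comprised ABIL1, AT2G46230, BAG6, LRB1, GBF3, TRIP-1 and AT2G46290. The median log2 difference of these 7 genes was 0.57 in mock and 0.64 in ABA libraries, and 6 and 5 of them were called. The same genes lay at -0.005 in J1721 and 0.005 in Q0990 in mock libraries.

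**Figure D5:**
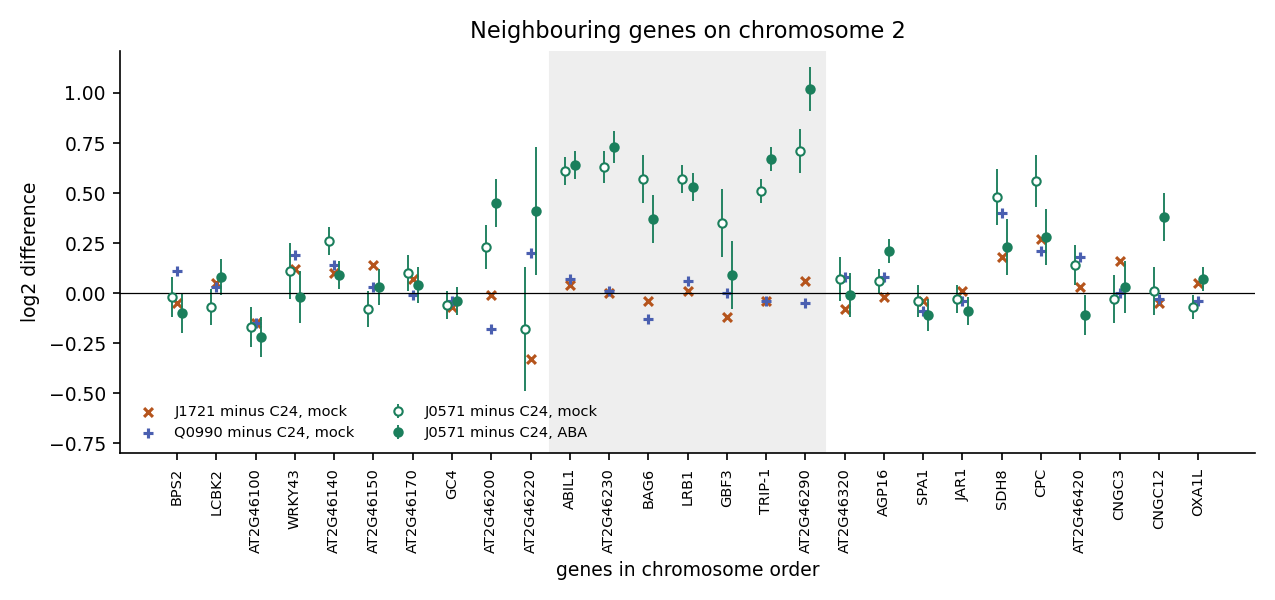
Log2 difference from C24 (vertical axis, with SE for J0571) of genes in their order along chromosome 2, for J0571 in mock and ABA libraries and for J1721 and Q0990 in mock libraries (crosses). The shaded run of 7 genes is raised in J0571, with a median of 0.57 in mock libraries.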

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

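Of the tests in this part, those of the chromosome 2 segment, of the root zone and of the left-out C24 mock library were chosen only after the results were seen; the others were fixed earlier.

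The ABA response differed between lines by a direct test of the difference in the following results. Between J0571 and C24, 86 genes differed; between J1721 and C24, 36; between J0571 and J1721, 65; between J0571 and Q0990, 83; and between J1721 and Q0990, 5. In J0571 the ABA receptor list differed from C24 by a median of 0.292, the LEA and dehydration list by -0.444, and the root hair and epidermis list by -0.426. These 3 list calls were lost with an estimated correlation (adjusted p = 0.0753, 0.051 and 0.0753 with an estimated correlation). The VND factors and xylem regulators differed by -0.467 and the secondary wall and vessel death genes by -0.464 in J1721, and genes lowered by ABA differed by 0.304 in J0571.

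Other splits of the libraries were set against these counts. For the average ABA response chance is excluded, since only the real split, 1 of 30, called as many genes (11772, against 0 in the highest other). For the response of each line, 10 splits are too few for a share under 0.05; the real split, 1 of 10, called 7252, 5169, 6089 and 6651 genes in C24, J0571, J1721 and Q0990, against 0 in every other split. For mock libraries the splits are too few as well: J0571 had 101 against 1 in the highest other, Q0990 10 against 1, and J1721 9 against 46 in the split that put C24 mock library 1 with J1721 mock libraries 2 and 3. For the differences in response chance is not excluded, since 2 of 30 splits gave as many genes: for J0571 against C24 86 with 349 in the highest other, for J1721 against C24 36 with 86, for J0571 against J1721 65 with 136, for J0571 against Q0990 83 with 161 and for J1721 against Q0990 5 with 88. In each case the other split left the ABA libraries in their lines and exchanged 2 of 3 mock libraries. That exchange turns a difference between lines that both treatments share into an apparent response. It points to a structure of the samples and cannot decide on chance. The exchange was the same each time, since the same draw of splits served every difference. For Q0990 against C24, all 30 splits reached the real count of 0, with 1 in the highest other.

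The weak ABA response of secondary wall and vessel death genes in J1721 was not a feature of C24 alone, since the response in J1721 was also lower than the mean of J0571 and Q0990, by a median of -0.346 (-0.292 against Q0990 alone, and J0571 lay 0.39 above J1721). Roots collected from a zone of another age in 1 group would be expected to move suberin genes the same way, but their median difference in response was 0.122 (quartile deviation 0.087). Suberin genes themselves rose with ABA in every line, so this value is not a clean marker of root zone and cannot settle the point. The Casparian strip list, the other marker named for this, was not called in this difference (fry adjusted p = 0.856, direction lower). Chance is not excluded by the splits, of which 2 of 30 gave a median as large (-0.464, with -0.605 in the split described above). That split cannot decide on chance, for the reason given there. What stays open, untested by any contrast here, is that blocked ABA signalling in the cells of this driver may prevent the rise of xylem genes. A difference between the lines in the share of xylem cells, at the start or during the 8 h of treatment, stays open as well. So does a line difference outside the transgene, which cannot be separated from blocked signalling because each driver is represented by 1 line. In mock libraries the secondary wall list had a median of -0.166 in J1721 against C24 and was not called. The VND factors and xylem regulators were lower there, as given above, a call that depended on single libraries. These mock values cannot tell fewer xylem cells from a lower level per cell.

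The smaller fall of ABA-lowered genes in J0571 was also seen against the mean of J1721 and Q0990, at a median of 0.136, which rested on Q0990 (0.226) and not on J1721 (0.034). A lower starting level in J0571 was not found, as the 665 genes lay at 0.192 above C24 in mock libraries and 0.385 above it in ABA libraries. C24 mock library 1, which stands apart from its replicates, was not the whole source, since the median was 0.281 without it, though the adjusted p was then 0.0503; without J0571 mock library 1, which also stands apart, they were 0.259 and 0.0545. Chance is not excluded: 3 of 30 splits, the real one included, gave a median as large (0.304, against 0.461 in the highest other). The others as large, at 0.461 and 0.324, exchanged 2 of 3 mock libraries between the lines. That turns the higher level of these genes in J0571 in both treatments into an apparent response, so the splits cannot decide on chance. Blocked ABA signalling in the cells of the driver, and a line difference outside the transgene, may both account for the smaller fall. They cannot be separated because each driver is represented by 1 line.

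Of 6 scans of 15976 genes in their order, 1 per driver line and treatment, the 7 neighbouring genes on chromosome 2 led both scans of J0571, where 2 of 1000 shuffles of gene order gave as large a median in mock libraries (highest 0.636) and 7 of 1000 in ABA libraries; an unrelated run on chromosome 4 in ABA libraries of J1721 (AT4G27390 to AT4G27450, median -0.444) reached 15 of 1000. The ABA libraries, which are other samples, gave a median of 0.645, which argues against noise in the mock libraries. The larger of the medians in J1721 and Q0990 was 0.005, which argues against a response to the transgene shared by the driver lines. Each driver acts in its own set of cells, so a response to abi1-1 in the cells of J0571 alone stays open. The mean difference was 0.564 ± 0.044 in mock and 0.581 ± 0.11 in ABA libraries, where 3 copies in place of 2 would give 0.585. These SEs are taken over the 7 genes, which share the same pools, and do not measure error between libraries. The run was also picked for its mock median, so its closeness to 0.585 is limited evidence. In mock libraries the 7 genes scattered about 0.585 no more than their errors from the fit (chi-square 5.48, limit 14.1). In ABA libraries the genes did not share that value (chi-square 33.3), with GBF3 at 0.09 ± 0.17, BAG6 at 0.37 ± 0.12 and AT2G46290 at 1.02 ± 0.11, which argues against an extra copy as the only difference there. An extra copy together with a differing ABA response of some of these genes, and an effect of a driver insertion near them, may each account for the run, and neither was tested.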

How the results depend on the processing

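The leave-out fits of the gene lists were tests chosen only after the results were seen; the other alternatives were planned. Named genes kept their direction and side of the threshold in 749 of the fits under other settings and lost the call in 49, and gene list calls were kept in 148 and lost in 41; with 1 library left out, the numbers were 729 and 219 for named genes and 362 and 46 for lists. Relative log expression normalization changed no count by over 1.5 times and no median of all genes by over 0.1. The cause of the changes below was not tested unless a reason is given.

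With an absolute log2 change of at least 1, a stricter rule, the ABA responses held 1860 genes in C24, 1338 in J0571, 1565 in J1721, 1683 in Q0990 and 1816 in the average, with 641 raised and 226 lowered in all 4 lines. Differences in response held 42 genes for J0571 and 16 for J1721 against C24, 37 for J0571 against J1721 and 43 for J0571 against Q0990; mock differences held 32 for J0571 and 5 for J1721. DESeq2 called 197 genes for J0571 against C24 (91 higher and 106 lower, against 59 and 27 by edgeR), 62 for J1721, 3 for Q0990, 135 for J0571 against J1721, 187 for J0571 against Q0990 and 12 for J1721 against Q0990, and 282, 39 and 16 in mock libraries of J0571, J1721 and Q0990. In the simulated counts DESeq2 made more false calls than edgeR (12.1 against 5.9% for a response and 10.7 against 4% for a difference in response). With only the groups compared in the fit, J1721 against C24 gave 15 genes, J1721 against Q0990 0 and mock J0571 39, from fewer samples. With no filter on low counts, Q0990 against C24 gave 1. The difference of ABA-raised genes in J0571 passed with no fold threshold (-0.088, adjusted p = 0.0106) and over the LEA and dehydration list (-0.444, adjusted p = 0.0046). The latter is the fry test of that list given above, adjusted over fewer tests, so it is not separate support. Camera with an estimated correlation lost that call (adjusted p = 0.051). Of 220 list tests 63 were called by fry and 24 by camera with an estimated correlation.

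Replicate numbers were not taken to pair the libraries, since the labels do not say so and no within-line correlation of libraries with the same number passed 0.1. Within lines, deviations of ABA and mock libraries with the same number correlated at -0.069 to 0.097 (12 pairs), and 15 of 24 libraries correlated best with their own number where chance gives 8, a hint of pairing from the data and not from the design. With the number within a line as a block, J1721 against C24 gave 11 genes, J0571 against J1721 43 and J1721 against Q0990 3. With a block shared by all lines no count moved by over 1.5 times, and the aquaporin list in mock J0571 (adjusted p = 0.0535) and the iron deficiency list in C24 (0.0646) lost their calls.

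Leaving out each library in turn gave 57 to 90 genes for J0571 against C24, 8 to 34 for J1721 against C24, 0 to 1 for Q0990 against C24 (1 without C24 ABA library 2 or 3), 41 to 69 for J0571 against J1721, 45 to 99 for J0571 against Q0990 and 0 to 7 for J1721 against Q0990. Mock differences ran from 26 to 77 in J0571, 5 to 9 in J1721 and 6 to 17 in Q0990. The ABA responses stayed within 1.5 times of their counts, at 6169 to 6938 genes in C24, 4238 to 5092 in J0571, 5091 to 5493 in J1721 and 5576 to 5971 in Q0990. The median difference from C24 of raised genes ran from -0.289 to -0.135 in J0571, passing the test without C24 ABA library 3 (-0.272, adjusted p = 0.0463), and that of lowered genes from 0.191 to 0.362. In J1721 raised genes ran from -0.111 to 0.054, with a change of sign without C24 ABA library 1 (0.054), J1721 ABA library 1 (0.048), J1721 mock library 2 (0.005) or J1721 mock library 3 (0.026), and lowered genes from 0.052 to 0.284, passing the test without C24 ABA library 3 (0.284, adjusted p = 0.0463) or J1721 ABA library 2 (0.257, 0.0106). In Q0990 lowered genes ran from -0.055, without Q0990 ABA library 2, to 0.134. Depth limits what can be said of genes absent from mock libraries, whose folds are lower bounds, and in the simulated counts differences in response of 1.5-fold were mostly missed.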

Other observations

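Several genes, among those that differed between lines without ABA, were nearly absent from some lines and abundant in others in both treatments; no test was added for them after the results were seen. AT2G15555 had 2920 to 3514 counts per mock library in J0571 and 3050 to 3329 in Q0990, against 0 to 4 in C24 and 12 to 45 in J1721. AT3G06955 had 130 to 182 counts in J0571 mock libraries and 129 to 157 in those of Q0990. AT4G16215 had 3423 to 3469 counts in Q0990 mock libraries, against 0 to 1 in C24, 0 to 11 in J0571 and 1 to 14 in J1721, and AT2G05695 had 284 to 349 counts in Q0990 mock libraries. With ABA, Q0990 libraries had 2413 to 3094 counts of AT4G16215, below the range in mock libraries though not called as changed (-0.37 ± 0.40), and 320 to 352 of AT2G05695. Among the C24 ABA libraries, library 1 alone had more than 1 count of any of the 4: 48 for AT2G15555, 96 for AT4G16215, 18 for AT2G05695 and 6 for AT3G06955, against 0, 0, 0 and 0 to 1 in libraries 2 and 3. Without it 64 genes differed in response between J0571 and C24 and 27 between J1721 and C24, and the receptor, LEA and root hair list calls in J0571 were lost (edgeR fry adjusted p = 0.066). The source of these counts was not tested.

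CASP5 rose in all 4 lines, by 1.60 ± 0.20 in C24, 1.88 in J0571, 1.71 in J1721 and 1.39 in Q0990, and its response in J0571 was not called as different from that in C24 (0.27 ± 0.30, edgeR adjusted p = 0.901), while its level in J0571 was lower in both treatments.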
